A study of Mus musculus with 8 samples.

How the data were processed

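Tongue bud RNA of mouse embryos at embryonic day 13.5 was extracted with a column kit, labelled as biotin cRNA and hybridised to one-colour Affymetrix arrays, per the labels' protocols, with 4 control (Alk5 fl/fl) and 4 mutant (Wnt1-Cre; Alk5 fl/fl) samples, each numbered 1 to 4 in the sample titles. The values deposited by the authors are log2 expression values per probe set, and RMA is the tool named in the submitters' processing notes. RMA subtracts background, makes the arrays' distributions alike and summarises the probes of a set on a log2 scale, so small shifts common to many genes can be removed before any test. The version and settings of RMA are not given in the sources used here, and the scale was checked from the values, which hold no negative and 0 missing entries. Array medians of 5.96 to 6.01 show that the columns were aligned but not identical. Probe signal of 3' against 5' control probe sets differed between arrays by little: the log2 difference for Gapdh ran from −0.0349 to 0.0737 and for actin from 0.489 to 0.561.

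Probe sets were named through the platform annotation. Of 45101 probe sets, 64 were Affymetrix controls, 34945 named 1 gene, 932 named several and 9160 were unnamed. Those with several names or none were left out of the gene tests. Of the sets naming 1 gene, 34741 matched a RefSeq gene identifier (assembly GRCm38.p6) and 0 symbols changed. No genome build is named for the array values, so no coordinates are given, and probe set identifiers stand for identity. Each gene was represented by the probe set with the highest mean over all 8 arrays, and no filter on dim probe sets was applied. Of the 468 entries of the gene lists, 25 had no probe set naming that gene alone and were not analysed here.

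Mutant and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust options, two-sided) over 18193 genes with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p of 0.05. In the text rose, fell, higher and lower refer to mutants relative to controls, and a probe set's log2 change is the difference of group means. SE is the moderated standard error. The estimated prior degrees of freedom were 3.4. The design, the gene lists and the rule for named genes were fixed before the data were examined. Named genes were Tgfbr1, the 10 largest positive and 10 largest negative log2 changes among called genes whose 4 mutant values all lay on one side of the 4 control values, the 4 members with the smallest p of each list, and any list member that passed. Members outside this rule are named only as not having passed.

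The 25 lists tested were TGF-beta pathway components, TGF-beta response genes, myogenic progenitor and regulatory factors, contractile and differentiated muscle genes, tendon and muscle connective tissue genes, extracellular matrix genes, cranial neural crest mesenchyme transcription factors, genes of BMP, FGF, Hedgehog and Wnt signalling, markers of epithelial, endothelial, erythroid, macrophage and leukocyte, neuronal, Schwann and glial, cartilage, bone, and smooth muscle and pericyte cells, cell cycle genes, p53 response genes, hypoxia and glycolysis genes, immediate early and heat shock genes, and anterior Hox genes. Some genes stand in more than 1 list, and the lists are not independent. Sex-linked genes were examined per array only. Lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 25 lists, beside camera with an estimated correlation and fry. At the preset correlation 12 lists passed, 9 lower and 3 higher. With the correlation estimated 0 passed after adjustment (2 at an unadjusted p under 0.05), and 13 passed fry, which asks whether a list's genes move on balance one way and does not compare them with other genes. These were not the same lists. The myogenic (fry adjusted p = 0.0553) and epithelial (0.167) lists passed camera only. The BMP (0.0207), FGF (0.013) and immediate early (0.0133) lists passed fry only. The list mean per array was tested by an exact two-sided permutation test over the arrays. Its smallest possible p with 4 against 4 arrays is 0.0286, which 12 lists reached and which adjusts to 0.0595 over the lists, so no list passes by that test after adjustment. Those 12 differ from the 12 of camera: they hold the FGF and immediate early lists but not the neural crest and epithelial lists.

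The procedure was tested on data simulated for 18193 genes from the means and spread of these 8 arrays, with independent noise for each gene. It recovered 73 of 100 genes changed by 0.5 and 99 of 100 changed by 1 on the log2 scale, with 4 false calls, and called 0 genes when no change was added. Genes of a list are correlated on the real arrays, so the simulation does not test the list calls. On the real arrays 32 of the 35 splits into 4 and 4 called at least 1 list. Alternatives covered the replicate number as a block, repeated quantile normalization, median centring, filters on the dimmest 30% and 50% of probe sets, other ways to combine probe sets, the variance model, array weights, a sex-chromosome covariate, a test without variance moderation, a fold minimum of 1.5 and leaving out each array in turn. The others were chosen after seeing the data: leaving out controls 1 and 3, and using the level of Malat1 as a covariate. Scan dates and other batch labels were not used here. Figures were drawn with matplotlib 3.10.9 and tables joined with pandas 2.3.3.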

Results

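RNA was measured in tongue buds, the embryonic tissue that becomes the tongue, of mouse embryos at embryonic day 13.5. The bud holds mesenchyme derived from cranial neural crest cells together with the myogenic precursors of the tongue muscles. Control embryos carried the Alk5 fl/fl genotype. Mutant embryos carried Wnt1-Cre with Alk5 fl/fl, so that Cre recombinase expressed in neural crest cells inactivates Alk5, the type I receptor of TGF-beta whose gene symbol is Tgfbr1. The stated purpose of the series was to learn how the loss of TGF-beta signalling in neural crest cells affects their interaction with myogenic precursors. Each group had 4 one-colour Affymetrix arrays, and 18193 genes were represented by a probe set naming that gene alone. The median log2 value of an array lay between 5.96 and 6.01. Pearson correlations between arrays, taken across probe sets, were 0.995 to 0.997 among controls, 0.996 to 0.998 among mutants and 0.992 to 0.995 between the groups. The first principal component held 45.2% of the variance and parted the mutant arrays from the controls, and the second, with 18.7%, spread the arrays within both groups. The log2 value of Malat1 was 9.02 to 9.80 on arrays with a positive position on the second component. It was 7.11 to 8.28 on those with a negative position, and the cause was not tested. Embryo sex was not determined according to the labels, and control 3 lacked Y-linked signal, with a mean log2 value of 3.09 over Eif2s3y, Kdm5d and Uty against 8.44 to 8.73 on the other arrays. The labels number the tongue buds without saying that each came from a separate litter. The p-values set the group difference against the spread between these samples within groups. If samples share a litter, that spread may understate the spread between independent litters. The number of arrays limits the precision.

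Tgfbr1, the targeted gene, was higher on the arrays labelled mutant. Its brightest probe set, 1420895_at, read 12.03, 12.12, 11.97 and 11.89 on controls 1 to 4 and 12.42, 12.42, 12.37 and 12.36 on mutants 1 to 4. The means were 12.00 ± 0.10 and 12.39 ± 0.03 (SD, n = 4 each), a log2 change of 0.39 (SE 0.058, adjusted p = 0.0034) or 1.31-fold. Both dimmer probe sets were also higher, by 0.82 for 1420893_a_at (adjusted p = 0.0116 over all probe sets) and by 0.52 for 1420894_at (adjusted p = 0.0414). The sources used here do not place these probes relative to the floxed part of the gene, and cells of the bud outside the neural crest keep an intact gene. The probe sets therefore check neither the deletion nor the labels, and every direction reported rests on the labels.

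The comparison of mutant with control tongue buds asked which transcripts of the whole bud differed between these genotypes. No group carried Wnt1-Cre without the fl/fl genotype, so effects of the transgene and of receptor loss cannot be told apart. Of the measured list members, 25 of 30 contractile genes, 10 of 20 tendon genes, 12 of 26 matrix genes and 6 of 14 neuronal markers fell in mutants, though with an estimated correlation 0 lists passed camera, while the genes for arginase, the neurofilaments and the transcription factors Dlx1 and Dlx2 were higher. Of 18193 genes, 1768 passed an adjusted p of 0.05 in limma, 764 higher and 1004 lower in the mutants. A change of at least 1.5-fold was shown by 124 of the higher and 333 of the lower genes, and 130 of the called genes changed at least 2-fold. In 1725 of the called genes all 4 mutant values lay on one side of all 4 control values, a separation seen in 3235 genes overall where chance gives 2.86%. With fewer arrays fewer genes passed: 1155 (456 higher) without control 2, 1143 (428 higher) without mutant 2, 1172 (485 higher) without mutant 3 and 1172 (465 higher) without mutant 4. Leaving out controls 1 and 3, the arrays farthest along the second component and without Y-linked signal, gave 1218 genes, 481 of them higher.

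Arg1, encoding the arginase that splits arginine into ornithine and urea, showed the largest rise in measured signal, from 4.88 ± 0.16 to 7.75 ± 0.28 (SD, n = 4 each), which is 7.27-fold (log2 change 2.86, SE 0.135, adjusted p = 1.19e-05). Igdcc3, a membrane protein of the immunoglobulin superfamily, rose 4.99-fold (log2 change 2.32, SE 0.058) on its brightest probe set, with 2 of its 3 probe sets higher. Gpr50, an orphan receptor related to the melatonin receptors, rose by 2.07 on the log2 scale, the collectin gene Colec10 by 1.86, the chemokine gene Cxcl13 by 1.84 and Crispld2, which encodes a secreted protein, by 1.76. The matrix protein genes Sned1 and Edil3 rose by 1.72 and 1.68, and Sall4, a zinc-finger transcription factor of stem cells and limb buds, rose by 1.64 with SDs of 0.05 and 0.10. Sphkap, which encodes an A-kinase anchoring protein, differed by 1.63 with SDs of 0.55 and 0.74 (adjusted p = 0.0241). Its call was lost without control 1 (log2 change 1.45), control 4 (1.49), mutant 2 (1.65) or mutant 4 (1.70), and without controls 1 and 3 together (1.56). In all it was lost in 8 of the 22 alternatives, at an adjusted p of up to 0.0985. The control means of Arg1, Gpr50, Colec10, Sall4 and Sphkap lay below the array medians, and no detection call was used, so their folds and ranks hold for the measured signal only.

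Atp1b4, a muscle gene related to the beta subunits of the sodium pump, showed the largest fall in measured signal, from 8.11 ± 0.55 to 5.34 ± 0.62 (SD, n = 4 each; log2 change −2.77, SE 0.334, adjusted p = 0.00128). Next came Vip, encoding vasoactive intestinal peptide, at −2.04, Stmn2, a neuronal regulator of microtubules, at −1.95, Arfgef3 at −1.91 and Scg5, a chaperone of prohormone convertase, at −1.91. Tceal7 changed by −1.89, the membrane lectin gene Chodl by −1.83, the secreted factor gene Angptl1 by −1.77 and the matrix gene Cilp by −1.76. Vwc2, which encodes a secreted antagonist of BMP, changed by −1.74 on its brightest probe set, and its call rested on that set, whose probes can match other transcripts. With such probe sets left out the log2 change was −0.13 (adjusted p = 0.487). The mutant means of Atp1b4, Vip, Arfgef3 and Scg5 lay below the array medians, with the same limit.

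**Figure D1:**
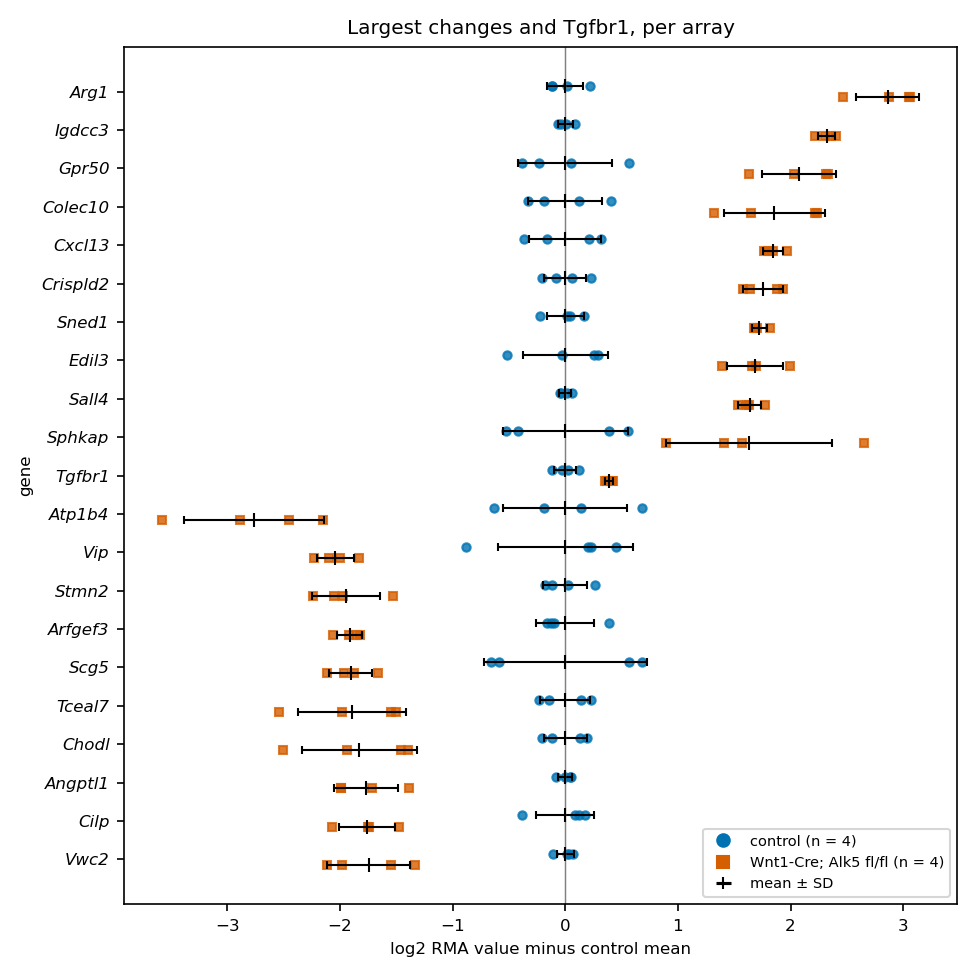
Log2 value of each array minus the control mean (horizontal axis) for Tgfbr1 and the 10 genes with the largest called change in each direction, 1 gene per line, with circles for 4 control arrays, squares for 4 mutant arrays and bars for the mean ± SD of each group. The mutant arrays of Arg1 lie around 2.86 and those of Atp1b4 around −2.77, and Sphkap and Atp1b4 show the widest spread among mutants.

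Most differentiated muscle genes fell. Of 30 measured genes of contraction and muscle differentiation, 25 fell and 0 rose, and 29 fell when adjusted over the list alone. The mean over the list changed by −0.78 (SD 0.17 in each group of 4 arrays). Examples are Ldb3, a protein of the Z-disc, at −1.41 (SE 0.147), Tnnt3, troponin T of fast fibres, at −1.23, Myoz2, which binds calcineurin at the Z-disc, at −1.17, and skeletal actin Acta1 at −1.03. Casq2, a calcium store protein, changed by −0.85 and Chrng, the embryonic subunit of the acetylcholine receptor, by −0.70. Embryonic myosin Myh3 changed by −0.68 and cardiac actin Actc1, already abundant in embryonic skeletal muscle, by −0.35. Des, Neb, Xirp1, Ckm and Ttn did not pass. The list passed camera at a preset correlation (adjusted p = 5.75e-25) but not with an estimated correlation (adjusted p = 0.293 with an estimated correlation). Its exact permutation p was 0.0286, the smallest that 4 arrays against 4 allow, and all 4 mutant means lay below all 4 control means. With 1 array left out 23 to 28 of the 30 genes fell, and without controls 1 and 3 together 28 fell.

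Regulators of the muscle lineage moved less uniformly. Of 18 measured myogenic progenitor and regulatory factors, 5 fell and 1 rose, or 7 and 1 when adjusted over the list alone. Myf6, encoding the myogenic factor MRF4, changed by −1.27 (SE 0.237), Mef2c by −0.57 (adjusted p = 0.0035) and Myog, which encodes the myogenin that drives terminal differentiation, by −0.38 (SE 0.062). The mutant mean of Myf6, 5.46, lay below the array medians. Tcf21, a transcription factor of head muscle precursors and connective tissue cells, rose by 0.67. Myod1 changed by −0.31 and Mef2d by −0.24, and each lost its call in 6 of the 8 fits with 1 array left out, where Myod1 ranged from −0.36 to −0.26 and Mef2d from −0.28 to −0.21. Genes of undifferentiated precursors did not pass, among them Msc at −0.39 (adjusted p = 0.146), Pax3 at −0.34 (0.415), Eya1 at −0.27 (0.321), Pax7 at −0.20 (0.577), Lbx1 at 0.08 (0.456) and Myf5 at 0.10 (0.456). These changes run from falls as large as those of the called Myod1 and Mef2d to small rises, so they do not show that the precursors were unchanged. The list mean changed by −0.23 (SD 0.094 in each group), with an adjusted p of 0.0279 in camera, 0.447 with an estimated correlation, and an exact permutation p of 0.0286. Its call in camera was lost without control 3 (mean change −0.21), without mutant 3 (−0.18), and without controls 1 and 3 (−0.27), and in 6 of the 22 alternatives in all. The number of genes falling was 3 without control 2, mutant 2 or mutant 3 and without controls 1 and 3, and 2 both in the test without variance moderation and with the mean of all probe sets of a gene. With that mean Mef2c was −0.48 (adjusted p = 0.0891), Myod1 −0.19 and Mef2d −0.18, and none of these 3 passed. On the same arrays the mean of macrophage and leukocyte markers changed by −0.43, that of Schwann cell and glial markers by −0.40 and that of endothelial markers by 0.24.

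**Figure D2:**
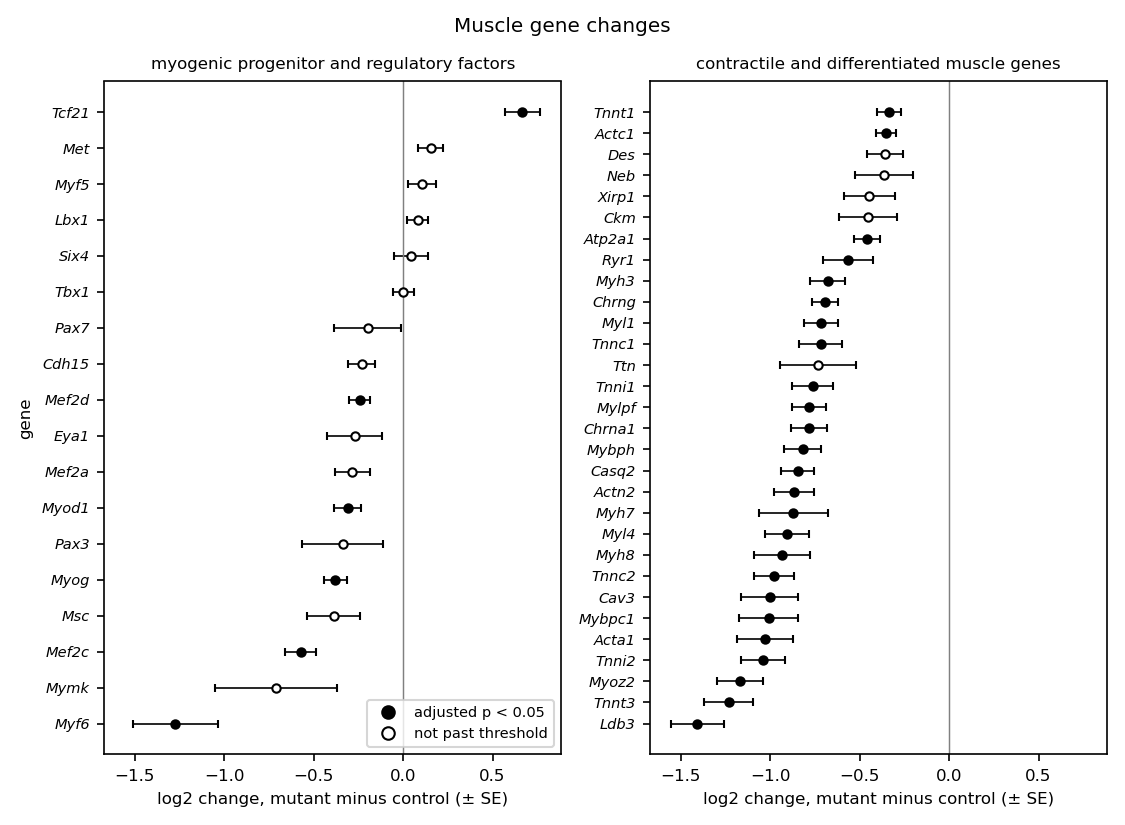
Log2 change, mutant minus control, with its SE (horizontal axis) for each measured gene of the 2 muscle lists, from 4 arrays per group, with filled circles for genes past an adjusted p of 0.05 and open circles for the others. All 30 contractile genes lie below 0, from −0.34 for Tnnt1 to −1.41 for Ldb3, while the regulatory factors run from −1.27 for Myf6 to 0.67 for Tcf21.

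Of 20 measured tendon and muscle connective tissue genes, 10 fell and 1 rose, or 11 and 1 adjusted over the list alone. Thbs4, a matrix protein of tendon and muscle attachment, changed by −1.70 (SE 0.125, adjusted p = 0.0001), Chodl by −1.83, Ogn, encoding the small leucine-rich proteoglycan osteoglycin, by −1.05 and the growth-response transcription factor gene Egr2 by −0.36. Both group means of Egr2, 4.80 and 4.45, lay below the array medians. Scx, the tendon transcription factor scleraxis, changed by −0.45, with its call lost without control 4 (−0.44) or mutant 4 (−0.42). The proteoglycan gene Lum differed the other way, by 0.58, and lost its call in 6 of the 8 fits with 1 array left out (0.42 to 0.67). The list mean changed by −0.48 (SD 0.14 in controls, 0.094 in mutants) with a camera adjusted p of 4.93e-05, an adjusted p of 0.287 with an estimated correlation and an exact permutation p of 0.0286. Without controls 1 and 3, 8 genes fell. Macrophage marker means (−0.43) and endothelial marker means (0.24) moved on the same arrays as these genes and the matrix genes.

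Extracellular matrix genes fell in 12 of 26 measured cases and rose in 2, or 14 and 2 adjusted over the list alone. Eln, which encodes elastin, changed by −1.04 (SE 0.075), Mfap4, a protein of elastic fibres, by −0.64, Fbln5, needed for elastic fibre assembly, by −0.93 and the proteoglycan gene Bgn by −0.82. Col6a1 and Col6a2 changed by −0.92 each and Col6a3 by −0.73. Vcan, encoding the proteoglycan versican, rose by 0.63 but did not pass without controls 1 and 3 (0.46, adjusted p = 0.1). Of its 8 probe sets 6 were higher, and with the mean of all probe sets Vcan was 0.29 and did not pass (limma adjusted p = 0.0547). Col3a1 differed by 0.24 and lost its call in each of the 8 fits with 1 array left out (0.21 to 0.27). The list mean changed by −0.32 (SD 0.05 in controls, 0.1 in mutants; camera adjusted p = 8.07e-05), with an adjusted p of 0.293 with an estimated correlation and an exact permutation p of 0.0286.

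Components of the TGF-beta pathway moved in both directions, with 3 of 19 rising and 5 falling, or 3 and 7 adjusted over the list alone. The ligand gene Tgfb3 changed by −0.67 (SE 0.094) and the type II receptor gene Tgfbr2 by −0.47, while the co-receptor gene Tgfbr3 rose by 0.36, as did Tgfbr1 by 0.39. With the mean of all probe sets Tgfbr2 was −0.21 (adjusted p = 0.0730) and Tgfbr3 0.19 (adjusted p = 0.0942), and neither passed. Ski and Ltbp1, also among the 5, each lost their call in 7 of the 8 fits with 1 array left out (−0.25 to −0.19 and −0.40 to −0.27). The number falling was 3 without control 2, control 4, mutant 1, mutant 2 or mutant 3, and without controls 1 and 3 it was 2, with 1 rising. The list mean was −0.06 and the median 0.02, and camera found no shift (adjusted p = 0.975). Of 18 measured TGF-beta response genes, 6 fell and 1 rose, or 8 and 1 adjusted over the list alone. The gene that rose, Tgif1 at 0.24, lost its call in 7 of the 8 fits with 1 array left out (0.20 to 0.28), and Bhlhe40 at −0.54 in 4 of them (−0.65 to −0.45). The number falling was 4 without control 2 or mutant 4. Bgn changed by −0.82, Tagln, an actin-binding protein of smooth muscle, by −0.88, Pmepa1, a feedback inhibitor of TGF-beta signalling, by −0.47 (SE 0.085) and Col1a1, a chain of collagen I, by −0.65. Acta2 differed by −0.26 on a probe set that can match related actins, and by 0.10 (adjusted p = 0.753) with such sets left out. The response list mean changed by −0.20 (SD 0.044 in controls, 0.061 in mutants; camera adjusted p = 0.028, adjusted p = 0.293 with an estimated correlation, exact permutation p = 0.0286). Its camera call was lost without control 1 (mean change −0.20), without control 2 (−0.19) and without controls 1 and 3 (−0.20). In all it was lost in 4 of the 22 alternatives, at an adjusted p of up to 0.136.

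Genes of BMP signalling rose in 5 of 22 measured cases and fell in 0, or 5 and 3 adjusted over the list alone. They were Bambi, a pseudoreceptor induced by BMP, at 0.67 (SE 0.088), Id2 at 0.54, the inhibitory Smad gene Smad6 at 0.45, Id3 at 0.39 and Id1 at 0.33, each of which is a known target of BMP signalling. The list mean was 0.06 (SD 0.039 in controls, 0.043 in mutants) and did not pass camera (adjusted p = 0.133, or 0.293 with an estimated correlation). The BMP list passed fry (adjusted p = 0.0207), with an exact permutation p of 0.0857. Of 21 FGF signalling genes, 3 fell and 1 rose, with the same counts adjusted over the list alone. Fgf6, a ligand gene of muscle, changed by −1.18 (SE 0.126), and the feedback inhibitor genes Spry1 and Spry4 by −0.67 and −0.61. Fgfr2 differed by 0.36, with its call lost without mutant 2 (0.34) or mutant 3 (0.33). The FGF list mean of −0.16 did not pass camera (adjusted p = 0.0615, or 0.293 with an estimated correlation). That list passed fry (adjusted p = 0.013), with an exact permutation p of 0.0286.

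Hedgehog genes rose in 2 and fell in 1 of 12 cases, or 3 and 2 adjusted over the list alone, with Gli3 at 0.30, Gli1 at 0.37, Gas1 at −0.37 and Ptch1, which did not pass, at 0.35. All 3 calls were lost in some fits with 1 array left out, 6 of the 8 for Gli3 (0.26 to 0.36) and for Gli1 (0.31 to 0.43) and 3 for Gas1 (−0.44 to −0.31). Wnt genes rose in 1 and fell in 1 of 24 cases, or 0 and 1 adjusted over the list alone. Nkd2, an inhibitor of Wnt signalling, changed by −0.65 but did not pass without controls 1 and 3 (−0.51), and the inhibitor gene Dkk1 differed by 0.53 but lost its call in 7 of the 8 fits with 1 array left out (0.39 to 0.61). Rspo2 at 0.59 and Wnt16 at −0.55 did not pass. The Hedgehog list mean was 0.02 (camera adjusted p = 0.435) and the Wnt list mean −0.01 (0.0062 with each array centred on its median), where the median was −0.04 and camera gave an upward direction (adjusted p = 0.994).

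Transcription factors of cranial neural crest mesenchyme rose in 5 of 28 measured cases and fell in 2, or 6 and 2 adjusted over the list alone. The homeobox genes Dlx2 and Dlx1 rose by 1.10 (SE 0.08) and 0.92 (SE 0.068), Barx1 by 0.67, Prrx1 by 0.76 and Gsc by 0.64. Pax9 fell by 0.81 and Tfap2b fell by 1.5 (SE 0.26). The list mean was 0.10 higher (SD 0.074 in controls, 0.051 in mutants) with a camera adjusted p of 0.0337, an adjusted p of 0.293 with an estimated correlation and an exact permutation p of 0.114. That camera call was lost without control 3 (0.084), control 4 (0.083), mutant 3 (0.078) or mutant 4 (0.095), and in 10 of the 22 alternatives in all, at an adjusted p of up to 0.139. Without control 1, 8 of these genes rose. Prrx1 did not pass without controls 1 and 3 (0.67, adjusted p = 0.101). Among 11 anterior Hox genes 0 passed, and Hoxa3 at −0.27, Hoxb3 at −0.14, Hoxd3 at −0.22 and Hoxa2 at −0.65 had the smallest p-values. Cartilage markers rose in 1 and fell in 1 of 15 cases, the collagen IX genes Col9a1 at 1.0 (SE 0.117) and Col9a3 at −0.45 (−0.41 and not passing without controls 1 and 3), with Matn4 at −0.38 and Cnmd at −0.94 not passing. Without control 4, 2 cartilage markers fell. Of 7 bone markers Dmp1 alone passed, at −0.63, and it was −0.20 (adjusted p = 0.19) without probe sets that can match other transcripts. Phex at −0.73, Sp7 at 0.03 and Ibsp at 0.05 did not pass. Camera adjusted p-values were 0.435, 0.91 and 0.495 for the Hox, cartilage and bone lists, and the bone list mean was −0.18 with a median of 0.0074.

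Neuronal markers moved apart. Of 14 measured, 6 fell and 2 rose, or 9 and 2 adjusted over the list alone. Stmn2 changed by −1.95, Tubb3, the neuronal tubulin, by −1.38 (SE 0.08), the RNA-binding protein gene Elavl4 by −1.22 and Phox2a, a transcription factor of autonomic neurons, by −0.79. Both group means of Phox2a, 5.93 and 5.15, lay below the array medians. The neurofilament genes Nefl and Nefm instead rose by 1.63 (SE 0.13) and 1.53 (SE 0.155), which is 3.09-fold and 2.89-fold. The list mean changed by −0.30 (SD 0.097 in controls, 0.061 in mutants; camera adjusted p = 0.00687, adjusted p = 0.293 with an estimated correlation, exact permutation p = 0.0286), and it did not pass camera when the dimmest 50% of probe sets were left out (−0.22, adjusted p = 0.112). Schwann cell and glial markers fell in 4 of 10 cases, or 7 adjusted over the list alone, and 0 rose. Ednrb, the endothelin receptor B, changed by −1.0 (SE 0.057), S100b by −0.39, Foxd3 by −0.37 and Sox10 by −0.35. Foxd3 lost its call in 3 of the 8 fits with 1 array left out (−0.43 to −0.30), as did Sox10 (−0.39 to −0.28). With the mean of all probe sets of a gene Sox10 was −0.13 and did not pass (limma adjusted p = 0.304). The number of glial markers falling was 2 without mutant 4, 6 without mutant 1 and 1 with the sex-chromosome covariate. The glial list mean changed by −0.40 (SD 0.14 in controls, 0.17 in mutants; camera adjusted p = 0.000188, adjusted p = 0.293 with an estimated correlation, exact permutation p = 0.0286).

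Markers of blood vessels and of immune cells moved in opposite directions. Endothelial markers rose in 4 of 15 cases, or 7 adjusted over the list alone, and 0 fell. The cadherin gene Cdh5 rose by 0.51 (SE 0.077) and Pecam1 by 0.34, and Sox18 at 0.31 and Esam at 0.18 lost their calls in 4 and 7 of the 8 fits with 1 array left out (0.26 to 0.34 and 0.17 to 0.20). Without mutant 1 or mutant 2, 2 of the endothelial markers rose, while 1 rose with the replicate block and 8 with the Malat1 covariate. Their list mean was 0.24 higher (SD 0.046 in controls, 0.11 in mutants; camera adjusted p = 2.46e-05, adjusted p = 0.293 with an estimated correlation, exact permutation p = 0.0286). Macrophage and leukocyte markers fell in 7 of 14 cases, or 10 adjusted over the list alone, and 0 rose. The chemokine gene Pf4 changed by −0.72, the receptor gene Csf1r by −0.60, the coagulation factor gene F13a1 by −0.76 and Adgre1, a surface marker of macrophages, by −0.52. Their list mean changed by −0.43 (SD 0.063 in controls, 0.21 in mutants; camera adjusted p = 2.46e-05, adjusted p = 0.293 with an estimated correlation, exact permutation p = 0.0286). Csf1r (−0.73 to −0.50), F13a1 (−0.94 to −0.63) and Adgre1 (−0.63 to −0.44) each lost their call in 5 of the 8 fits with 1 array left out. The number of these markers that fell ranged from 1 to 10 with 1 array left out and was 0 without controls 1 and 3.

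Epithelial markers fell in 1 of 19 cases, the keratin gene Krt18 at −0.34, which lost its call in 6 of the 8 fits with 1 array left out (−0.41 to −0.31), with Krt8 at −0.31, Cldn7 at −0.29 and Cdh1 at −0.29 not passing. Without control 1 or mutant 4, 3 of these markers fell. The list mean of −0.20 (SD 0.1 in controls, 0.19 in mutants) passed camera (adjusted p = 0.00216) but neither with an estimated correlation (adjusted p = 0.508) nor by exact permutation (p = 0.114), and not without mutant 1 (−0.13, camera adjusted p = 0.077). Smooth muscle and pericyte markers fell in 3 of 12 cases, or 5 adjusted over the list alone: Tagln at −0.88, Cspg4, a proteoglycan of pericytes, at −0.46 and Acta2 at −0.26, which was 0.10 without probe sets that can match related actins, while Actg2 at −0.60 did not pass (list camera adjusted p = 0.0651). Cspg4 did not pass without control 2 (−0.43) or without controls 1 and 3 (−0.46), and without control 2 only 1 of the 12 fell. Among 11 erythroid markers 0 passed, with Gata1 at −0.24, Epb42 at −0.11, Slc4a1 at −0.24 and Klf1 at 0.12 (list camera adjusted p = 0.63).

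Of 25 cell cycle genes 3 rose, or 6 adjusted over the list alone, and 0 fell. They were Mcm3 at 0.37 (SE 0.061), Mcm2 at 0.21 and Mcm4 at 0.21, while Mcm6 at 0.17, Mcm5 and Mcm7 did not pass. Mcm2 and Mcm4 lost their calls in 7 of the 8 fits with 1 array left out (0.18 to 0.24 and 0.19 to 0.25). In the list 1 gene rose without control 2, without any 1 of the mutants and without controls 1 and 3. The number rising was 5 with median centring, 6 without the dimmest 50% of probe sets and 9 with the trend and robust variance model. The list mean was 0.10 higher (SD 0.029 in controls, 0.041 in mutants; camera adjusted p = 0.000328, adjusted p = 0.293 with an estimated correlation, exact permutation p = 0.0286). Of 14 genes responding to p53, Cdkn1a, an inhibitor of cyclin-dependent kinases, fell by 0.50 and Bbc3, which promotes apoptosis, rose by 0.31, while Ccng1 at −0.21 and Ei24 at 0.16 did not pass. With the mean of all probe sets of a gene Cdkn1a was −0.37 and did not pass (limma adjusted p = 0.196). Without mutant 1, 2 genes of the p53 list fell. That list had a mean of −0.02 where camera gave an upward direction (adjusted p = 0.975). Of 19 hypoxia and glycolysis genes 3 rose and 0 fell, namely Adm at 0.27, Ero1a at 0.25 and Pfkfb3 at 0.28, with calls lost in 6, 6 and 7 of the 8 fits with 1 array left out (0.22 to 0.31, 0.22 to 0.28 and 0.22 to 0.32), and Aldoa at −0.26 did not pass. Without control 1, 0 of them rose and 3 fell, Aldoa among them at −0.34, and without controls 1 and 3 neither direction had a call. That list's mean of 0.0031 and median of −0.04 had opposite signs (camera adjusted p = 0.91). Immediate early and heat shock genes fell in 4 of 15 cases, or 6 adjusted over the list alone, and 0 rose. Nr4a1 changed by −0.38, Btg2 by −0.32, Egr1 by −0.54 and Fos by −0.46. The call of Fos was lost without mutant 2 (−0.40) or mutant 4 (−0.44). The immediate early list did not pass camera (adjusted p = 0.0555, or 0.293 with an estimated correlation). It passed fry (adjusted p = 0.0133), with an exact permutation p of 0.0286.

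**Figure D3:**
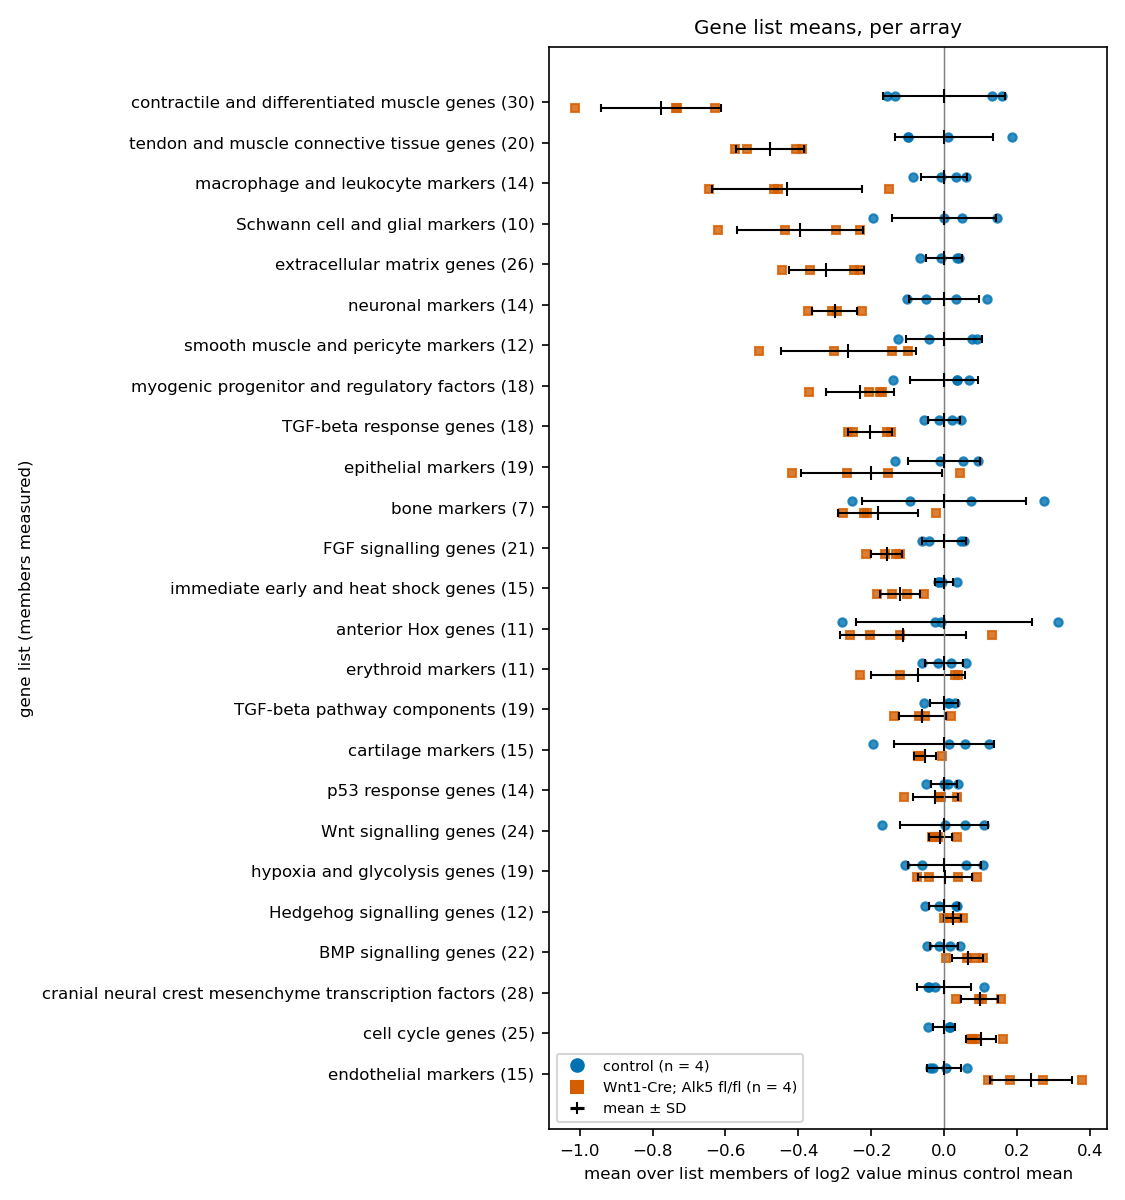
Mean over the measured members of each gene list of the log2 value minus the control mean (horizontal axis), 1 list per line with the number of members, with circles for 4 control arrays, squares for 4 mutant arrays and bars for the mean ± SD of each group. The contractile list lies lowest in mutants at a mean of −0.78 and the endothelial list highest at 0.24, and in 12 lists all 4 mutant arrays lie apart from all 4 controls, while in the others the arrays overlap.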

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

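An array was singled out here where its gap to the nearest of the other 3 arrays of its group took up most of the group's range, by Dixon's test. Chance singles out about 1 in 20 sets of 4 arrays, and the 24 cases below came from 350 sets for genes and 50 for lists. The tests of control 3 were set down before their results were seen.

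Control 3 read 3.36 for Eif2s3y, 3.31 for Kdm5d and 2.59 for Uty, where the other controls lay between 8.0 and 9.06. A female embryo with 2 X chromosomes is argued against by the 4 X-linked genes that escape inactivation (Kdm6a, Kdm5c, Eif2s3x and Ddx3x), whose mean in control 3 was 10.96 and lay 0.10 below the highest other array (difference −0.102, SD of the other arrays 0.088). Under a single X chromosome and no Y, that mean and the Xist signal should match the other arrays, and the escape mean differed from their mean by −0.015, but 1 of 3 Xist probe sets read 3.69 in control 3 against at most 3.68 on the other arrays (SD 0.174). Under the bound set beforehand that set is too high for a single X, yet by less than its spread. The other Xist sets read 5.85 and 3.16 in control 3, below the highest other array at 6.44 and 3.37. Thus no Xist set showed a rise in control 3 of more than 1 SD above all other arrays. The bound set beforehand therefore goes against an X0 embryo. An excess within 1 SD decides little, however, so an X0 embryo is neither excluded nor supported. No array here shows that the Xist probe sets respond to an inactive X. A Y chromosome lacking these genes or a sample from another stock was not tested.

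In the control group Arfgef3 read 7.90 on control 1 (others 7.36 to 7.42), Cilp 8.25 on control 3 (others 8.72 to 8.81), Col14a1 7.31 on control 3 (others 8.05 to 8.20) and Nefl 8.91 on control 2 (others 8.47 to 8.51). Epb42 and Mcm3 on control 4 read 4.88 and 11.3, where the others ran from 4.70 to 4.72 and from 11.40 to 11.43. In the mutant group Pmepa1 read 8.81, Fgf6 6.28, Phex 5.72, Aldoa 12.1 and Hoxa2 5.56 on mutant 1, with the others at 8.68 to 8.70, 6.80 to 6.87, 3.54 to 3.85, 11.83 to 11.84 and 4.23 to 4.41. Mutant 3 read 12.2 for Myog (others 12.38 to 12.40), 12.6 for Mylpf (others 12.89 to 12.94) and 7.30 for Dkk1 (others 6.72 to 6.74), and mutant 4 read 9.00 for Tnc (others 9.62 to 9.71) and 7.86 for Pax9 (others 7.37 to 7.45).

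Among list means, which are log2 values minus the control mean, control 1 stood apart for the myogenic regulatory factors at −0.139 (others 0.0350 to 0.0680) and for the cranial neural crest transcription factors at 0.110 (others −0.0442 to −0.0256). The cell cycle list stood apart on control 2 at −0.0438 (others 0.0122 to 0.0160) and on mutant 3 at 0.162 (others 0.0739 to 0.0885), and the cartilage list on mutant 1 at −0.00688 (others −0.0712 to −0.0628).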

How the results depend on the processing

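Leaving out controls 1 and 3 together and the Malat1 covariate were chosen after seeing the data, and the other settings before. The number of genes called, 1768, ranged from 1143 to 1583 with 1 array left out, the number higher from 428 to 623, the number lower from 687 to 960 and the number of lists from 10 to 14, with Tgfbr1 between 0.35 and 0.43. With the replicate number as a block 966 genes passed (329 higher, 637 lower) with 12 lists and Tgfbr1 again at 0.39. Same-numbered arrays did not deviate together (correlations of their deviations −0.40, 0.02, −0.18 and −0.16 for numbers 1 to 4). These values give no sign that the numbers pair the samples, but they cannot exclude it. A fold minimum of 1.5 left 457 genes (124 higher, 333 lower), and the test without variance moderation called 1238, 636 of them lower. In that test 0 of the macrophage markers fell (7 in the main fit), 5 tendon genes (10), 3 TGF-beta response genes (6) and 2 glial markers (4). Without controls 1 and 3, 1218 genes passed, 481 of them higher, with 10 lists. The Malat1 covariate gave 2049 genes and median centring 1874, 49.1% of them lower against 56.8%. In these settings 0 of the genes shared with the main result changed direction. With an estimated correlation 0 lists passed. Sphkap lost its call with the replicate block, with the trend and robust variance model and in the test without variance moderation, besides the 4 fits with 1 array left out named in the report and the fit without controls 1 and 3. Of the 146 called genes named besides Tgfbr1, 83 held in each fit run and Acta2 alone changed direction, to 0.10 without probe sets ending in _x_at or _s_at. Of the 12 called lists, 7 held in each alternative but the estimated correlation: the contractile, tendon, matrix, endothelial, macrophage, glial and cell cycle lists.

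The other changes of sign were of values that had not passed. For lists they were Wnt genes at 0.0062 with median centring, bone markers at 0.0079 and hypoxia genes at −0.0025 without the dimmest 50% of probe sets, the TGF-beta pathway at 0.019 and hypoxia genes at −0.0048 with the mean of all probe sets, these at 0.036 and −0.020 with every probe set on its own, hypoxia genes at −0.030 with array weights, and Hox genes at 0.038 with the sex-chromosome covariate. That covariate also gave Phex 0.054, Hoxd3 0.0081 and Hoxa2 0.12. With 1 array left out the hypoxia list ranged from −0.033 to 0.039, Ibsp from −0.074 to 0.17 and Sp7 from −0.0094 to 0.056, and without controls 1 and 3 Sp7 was −0.017 and the cartilage list 0.038. The cause of these changes was not tested. Dim genes were kept in the main fit, and no detection call on signal over background was used here.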

Other observations

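Chosen after their results were seen were the retinoid genes, the test of a smaller share of muscle-lineage cells, the test of fewer neurons as the whole neuronal pattern, the test of the Nefl probe sets alone and the splits of arrays for the gene count. The other tests were set down before their results.

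Genes of retinoic acid synthesis, response and breakdown, a list of 17 with 15 measured, moved both ways in the mutants. Aldh1a2, which makes retinoic acid in embryonic mesenchyme, rose by 1.34 (SE 0.24, 2.52-fold) and the receptor and target gene Rarb by 1.54 (SE 0.24, 2.90-fold). Aldh1a1 rose by 0.71 (limma adjusted p = 0.0319) and the binding protein gene Crabp1 by 0.40 (adjusted p = 0.0351). Both group means of Aldh1a1, 4.88 and 5.58, lay below the array medians. The retinoid genes were not followed through the alternatives. Aldh1a3, another synthetic enzyme, fell by 1.65 (SE 0.135) and Cyp26a1, which degrades retinoic acid, fell by 0.94. The remaining 9 genes did not pass in limma, among them Rdh10 at 0.25 and Cyp26b1 at −0.28.

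Most of the muscle genes measured were lower in mutants. The contractile change stayed at −0.761 or lower under repeated quantile normalization and median centring. Both steps started from the deposited RMA values, so an effect of RMA itself was not tested. If the mutant tissue held a smaller share of all muscle-lineage cells, 8 genes of early myogenic cells (Pax3, Pax7, Myf5, Lbx1, Met, Six4, Eya1 and Msc) should fall by about as much as the contractile list. Their mean changed by −0.10 (exact permutation p = 0.0857), and the contractile mean minus the early mean per array differed by −0.676 between the groups (exact permutation p = 0.0286, the smallest possible). These 8 genes leave out the 6 called genes of the list of myogenic factors fixed beforehand, so they exclude nothing. A smaller share of muscle-lineage cells and reduced or delayed differentiation therefore cannot be told apart here, and both stay open as hypotheses. A change in the makeup of the dissected tissue other than the muscle share was not tested.

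Fewer neurons as the cause of the whole neuronal pattern would lower every marker, while 2 called markers, Nefl and Nefm, were higher. These 2 genes define the pattern, so they are no separate test of that explanation. For Nefl, cross-hybridizing probes are argued against by 2 of 2 probe sets being higher and called. All 3 probe sets of the 2 genes were higher and called, but Nefm has 1 probe set, so for Nefm a change and cross-hybridizing probes cannot be told apart. For the falling markers fewer neurons stays open, since an independent list of 16 pan-neuronal genes changed by −0.381 (exact permutation p = 0.0286, the smallest possible), with 9 called lower, led by Stmn4 and Stmn3 at −1.21 each, and Sncg alone called higher at 0.75. Sncg, Nefl and Nefm are all abundant in peripheral sensory and motor neurons, so a candidate explanation is that kinds of neurons or their RNA changed unequally, which was not tested.

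The 8 arrays can be split into 4 and 4 in 35 ways. Only the real split called as many as its 1768 genes, and the highest other called 37. These counts argue against a chance split, but 1 of 35 is the smallest share possible, so they do not exclude it. The splits cannot address a litter or batch difference that runs with genotype. Chance cannot be excluded for the number of lists, since 6 of the 35 splits called at least the 12 of the real split and the highest other called 13.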
